A study of Mus musculus with 10 samples.

How the data were processed

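Per the labels, RNA came from mouse tail fibroblasts, from cells after lentiviral delivery of 3 factors (Foxa3, Gata4 and Hnf1a) and from mouse liver. The cells with the factors were sampled at days 2, 4, 6 and 14. RNA was extracted with Trizol and made into libraries with a TruSeq stranded mRNA kit. The labels give the strain as C57/B6 x 129sv and state that the medium of induced cells was replaced after 48 hours. They describe 10 libraries, 1 of fibroblasts, 2 at each of days 2, 4, 6 and 14, and 1 of liver. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.1, HTSeq and DESeq were used with the mouse build mm10; which tool gave the deposited values, and on which annotation, is not stated.

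The deposited table gives FPKM by the authors, 1 column for each of the 6 groups. Values of the fibroblast and liver columns have at most 6 significant digits. Of the values above 0 in the day columns, 51.2% to 52.4% carry 7 or more digits, and 93.9% to 96.2% of those end in 5, the pattern left by a mean of 2 such values. The day columns were therefore read as the authors' means of 2 libraries. No spread between libraries can be had from such means, so the planned model tests (limma, its F test and the camera and fry list tests) were not run, and no p-value is given. Values are set against each other by size alone.

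Of 24062 entries, 27 carry a number in place of a gene name, in the form that spreadsheet programs give to converted names, and were left out; they hold at most 0.174% of the total FPKM of a column. Of the 24035 named genes, 22859 names are in the GENCODE M21 annotation (GRCm38, the same assembly as mm10), which also gave the coordinates, and 23944 are found with RefSeq symbols and synonyms added. Genes are named by the symbols of the table, which has no other identifiers.

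Values were used as deposited, as log2(FPKM + 1), for the 14107 genes at 1 FPKM or more in at least 1 column. A gene was called higher or lower where the difference of 2 columns was at least 1 on this scale, a 2-fold difference of FPKM plus 1; a gene listed at 0 is given with its level and no fold. The main comparisons were day 2 and day 14 with fibroblasts, day 14 with day 2 and liver with day 14. Steps between successive days, and liver with fibroblasts, were counted too. In place of the F test over days, genes were counted whose highest and lowest day were at least 2-fold apart.

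Choices on comparisons, size rule, gene lists and naming rule were made before the data were examined. There are 26 lists: hepatocyte secreted proteins, metabolic enzymes, and detoxification and transport; endogenous liver transcription factors; fetal liver and bile duct progenitor; epithelial junction and keratin; intestinal and gastric endoderm; fibroblast and extracellular matrix; mesenchymal transcription factors; myofibroblast and smooth muscle; Hox genes; cell cycle; p53 and senescence; interferon response; inflammation and acute phase; cholesterol synthesis; chromatin and genome folding factors; markers of Kupffer cells and macrophages, liver endothelium, red blood cells, skin keratinocytes, skeletal muscle, cartilage and bone, fat cells, and glia and neurons; and widely expressed control genes. For each list the median difference was placed among those of 10000 random lists with as many genes from each of 20 bins of mean expression over the 6 columns. The central 95% of these medians runs from percentile 2.5 to 97.5.

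The naming rule took the 3 delivered factors first. For each main comparison it took the 8 largest differences each way, with predicted genes, Rik and LOC names and Mir and Snor genes skipped, and up to 4 members of each list with the largest absolute difference. For each step it took the 3 largest each way. The rule set no skipping for steps; the same skipping, with Rnu and Scarna genes added, was applied there after the values were seen. Its demand that genes pass a test and that libraries do not overlap could not be met. A gene taken in 1 comparison could be described in another, and genes outside the rule are marked as named after their values were seen.

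Genes at least 4-fold apart between liver and fibroblasts (a log2 difference of 2) were split by sign, and the share at least 2-fold toward liver was counted at each day. The simulation planned for these shares was not run. Genes picked on liver against day 2 were scored in its place, where the day 2 column also scores day 2. The overlap of gene calls was set against the number that independent picks would share.

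Depth is not stated. Among 582 genes under 0.3 FPKM in both lone libraries, 77.3% of the ratios of the 2 values lay on the steps that whole numbers of 1 to 6 fragments give, within 0.01 on the log2 scale, against 9.80% at random offsets. This put fibroblast depth at 2.08 times liver depth. From 18 genes with a single annotated transcript at 1 fragment, fibroblast depth was about 1.21e+07 fragments (quartiles 1.11e+07 and 1.26e+07) and liver depth 5.83e+06 (quartiles 5.33e+06 and 6.09e+06). At such depth 1 fragment moves a low FPKM value by a large share, most of all in short genes.

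Alternatives were a pseudocount of 0.1, a filter of 1 FPKM in at least 2 columns, no filter, median-ratio scaling, quantile normalisation, and a log2 difference of 3 to set liver and fibroblast genes. Added after the data were seen were the selection on day 2, random lists matched on the 2 columns compared, and leaving out genes whose longest annotated transcript is under 200 nt. Simulated data were the better expressed genes of the fibroblast column against itself, 8784 genes, with log2 noise of standard deviation 0.1. Of genes set at each of log2 differences 2, 3, -2 and -3, 50 of 50 were recovered, and 0 others reached a 2-fold difference. With noise this small both results followed from the settings, so they give no error rate for the deposited columns. Of 200 random lists, 93% lay inside the central 95%. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.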

Results

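RNA was sequenced from mouse tail fibroblasts (TTF), from cells to which lentivirus had delivered Foxa3, Gata4 and Hnf1a, 3 transcription factors of the developing liver and gut, to induce hepatocyte-like cells (iHep), and from mouse liver. The labels describe 10 libraries: 1 of fibroblasts at day 0, 2 each of induced cells at days 2, 4, 6 and 14, and 1 of mouse liver. The deposited table holds 1 column per group in FPKM, in which the authors scaled fragments to transcript length and to mapped fragments. The fibroblast column is headed p19-TTF, and the labels do not say whether p19 stands for a passage or for p19Arf, a product of Cdkn2a, so the fibroblast values of Cdkn2a and of the p53 and cell cycle lists are given with that reading open. The fibroblast and liver columns are single libraries, and each day column is the authors' mean of 2 libraries. The spread between libraries is not in the table, so no value has a replicate error, no difference could be set against one, and no test or p-value is given. Total FPKM per column was 623321 in fibroblasts, 589715 at day 2, 502206 at day 4, 476653 at day 6, 508995 at day 14 and 1471730 in liver. Genes listed at 1 FPKM or more numbered 10984 in fibroblasts, 11516, 11621, 11800 and 11992 at days 2, 4, 6 and 14, and 11699 in liver. The 10 most abundant genes held 20.3% of the total in liver and 12.4% to 13.7% in the other columns. Library depth is not stated. The spacing of the lowest values put fibroblast depth at 2.08 times that of liver, and about 1.21e+07 and 5.83e+06 fragments, while the depth behind the day columns could not be recovered.

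Differences are log2 differences of FPKM plus 1, over the 14107 genes at 1 FPKM or more in at least 1 column. A gene is called higher or lower where it differed at least 2-fold on that scale. Where the largest differences are named, predicted genes, Rik and LOC names and Mir and Snor genes are skipped, some of which differed more. Gene lists are described by their members among these genes called higher and lower, by their median difference, and by the range that holds the central 95% of 10000 random lists of like expression. Random lists draw genes independently, while members of a list can vary together, so a position among them is not a p-value. Members under 1 FPKM in every column were not counted, which left 20 of 30 intestinal and gastric genes, 21 of 30 mesenchymal transcription factors, 27 of 38 Hox genes and 17 of 20 fetal liver and bile duct genes. When the columns were quantile normalised, the differences of single genes shifted by a median of -0.17 for day 14 against fibroblasts, -0.12 for day 14 against day 2, -0.10 for liver against day 14 and -0.32 for liver against fibroblasts. The median shift was smaller than 0.1 in the other comparisons. These are medians over all genes, and sets of genes could shift by more. The widely expressed control genes did so for day 14 against fibroblasts and liver against day 14, as given below.

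The 3 delivered factors were near 0 in fibroblasts and abundant from day 2. Foxa3, a forkhead factor that opens liver chromatin (GRCm38, chromosome 7, 19013284 to 19023538), was listed at 0.480 FPKM in fibroblasts, 458 at day 2, 479 at day 4, 423 at day 6, 230.1 at day 14 and 49.98 in liver. Gata4, a zinc finger factor of endoderm and heart (chromosome 14, 63198922 to 63271692), was at 0.0689, 99.8, 70.3, 70.7, 72.8 and 8.63 FPKM in the same order. Hnf1a, a homeobox factor of hepatocytes (chromosome 5, 114948980 to 114971094), was at 0.172, 593, 545, 466, 264 and 28.8 FPKM. At day 14 all 3 were above their level in liver, Gata4 at 72.8 against 8.63 FPKM. These values may include RNA made from the vectors, which the table does not part from RNA of the cells' own genes.

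**Figure D1:**
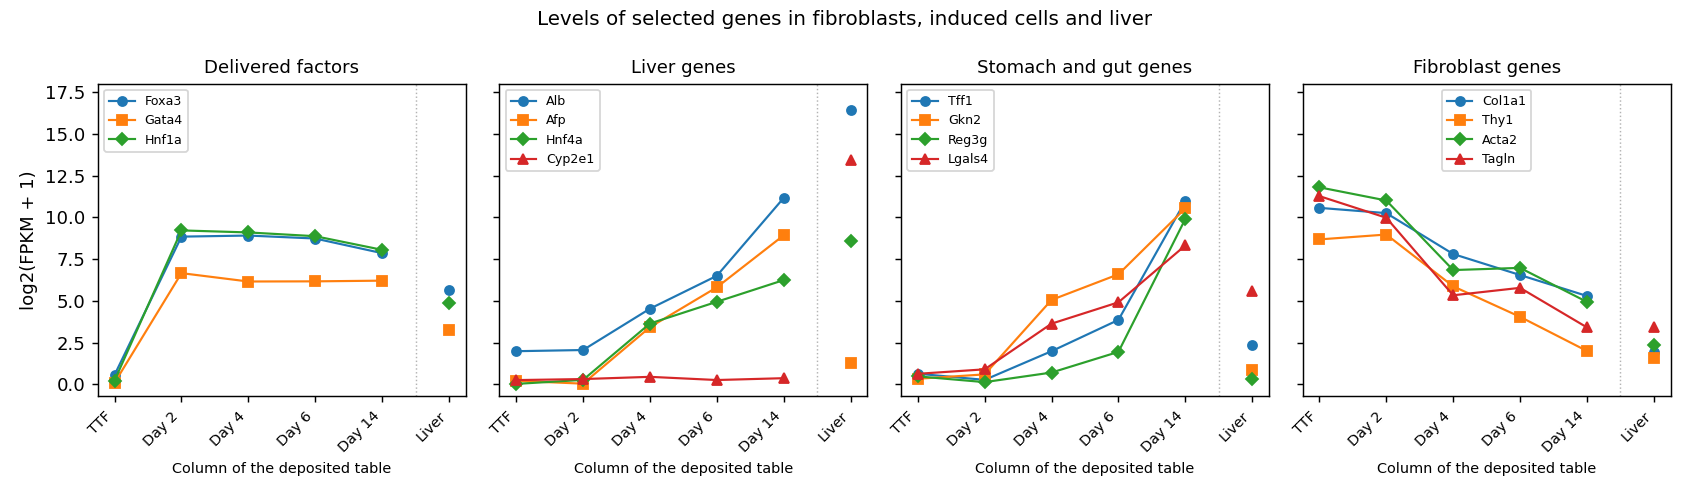
Levels of selected genes in the 6 columns of the deposited table, as log2(FPKM + 1) on the vertical axis, in 4 panels for the delivered factors, liver genes, stomach and gut genes, and fibroblast genes. Points are single libraries (TTF, Liver) or the authors' means (days), lines join fibroblasts and days, and the dotted line sets Liver apart; Alb, Afp, Tff1 and Gkn2 are highest among the days at day 14, while Cyp2e1 stays under 1 FPKM before liver.

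The comparison of day 2 with fibroblasts covers the first 48 hours. No column holds cells given virus without the factors, so a response to the factors is not separated from one to virus or culture. The labels put a change of medium after 48 hours, so days 4, 6 and 14 differ from day 2 in medium too, and no comparison with them separates the factors from the medium. Besides the factors, the day 2 column was marked by interferon response genes, which were higher nearly as a block, and by cell cycle genes, most of which were lower. Isg15, a ubiquitin-like antiviral protein, was 254 FPKM at day 2 against 9.03 in fibroblasts, and Ifit1, which binds viral RNA, 68.9 against 1.99. The mitotic regulator Birc5 was 20.1 against 123 FPKM. Albumin (Alb; chromosome 5, 90460897 to 90476602) was 3.15 FPKM at day 2 and 2.95 in fibroblasts. In all, 1467 of the 14107 genes were called higher and 1208 lower, and 330 and 125 of these differed at least 4-fold. With a pseudocount of 0.1 in place of 1, 2443 genes were called higher.

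Of the 25 interferon response genes measured, 22 were higher at day 2 and none lower, with a median log2 difference of 2.99 (above all 10000 random lists). The other 3, Rsad2, Mx1 and Cxcl10, named after their values were seen, passed in neither direction. Irf7, the transcription factor that amplifies interferon production, was 46.1 against 1.88 FPKM, and Ifit3 60.2 against 4.26. Of 30 cell cycle genes, 26 were lower and none higher (median -1.49, below all 10000 random lists). Rrm2, which makes deoxynucleotides, was 34.5 against 196 FPKM, and the replication helicase gene Mcm3 12.4 against 62.4. Of 24 cholesterol synthesis genes, 11 were higher and none lower (median 0.94, above all 10000 random lists). They included Pcsk9, whose protein removes the LDL receptor, at 186 against 10.5 FPKM, Tm7sf2, a sterol reductase, at 25.1 against 3.81, and the kinase gene Pmvk at 68.8 against 16.8. In the p53 and senescence list 3 of 16 genes were higher and none lower (median 0.42, random lists -0.39 to 0.44). These were Trp53inp1 at 16.3 against 2.81 FPKM, Gadd45a at 26.97 against 7.73 and Glb1, the lysosomal beta-galactosidase, at 58.1 against 22.6.

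Most matrix and myofibroblast genes differed from fibroblasts by less than 2-fold at day 2, as did 12 of 21 mesenchymal transcription factors. The other 9 of these factors were lower and none was higher (median -0.87, below all 10000 random lists), among them Foxc2 at 1.72 against 9.71 FPKM and Snai1, a repressor of epithelial genes, at 9.13 against 29.5. Of 29 extracellular matrix genes, 3 were higher (Pdgfra, Fn1 and Dcn) and 2 lower (Col6a3 and Loxl1), with a median of -0.06; Dcn was named after its values were seen. Fibronectin (Fn1) was 1472 against 674 FPKM, and Col6a3, a collagen VI chain, 47.6 against 148. In the myofibroblast list 4 of 15 genes were lower (Serpine1, Cnn1, Tagln and Actg2) and 1 higher (Ctgf, 2421 against 1197 FPKM), with a median of -0.31 (random lists -0.32 to 0.43). Of 27 Hox genes, which set position along the body axis, Hoxc6 and Hoxb3 were higher and none lower (median 0.46, random lists -0.13 to 0.32; 0.33 after quantile normalisation). In the chromatin list 4 of 27 genes were lower (Dnmt1, Ezh2, Smc3 and Stag1) and none higher (median -0.31, random lists -0.35 to 0.34).

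Of the 30 hepatocyte secreted proteins, 4 were higher at day 2: Kng1, the kininogen gene, at 28.1 against 1.01 FPKM, the copper carrier Cp at 12.97 against 0.316, transferrin (Trf) at 16.1 against 0.930 and Rbp4 at 1.83 against 0.408. Of 30 detoxification and transport genes, 4 were higher (Cyp2d22, Cyp27a1, Cyp2f2 and Ephx1), and of 30 metabolic enzymes Fah was higher at 45.4 against 14.4 FPKM and Ass1 lower at 2.19 against 16.1. None of the 23 liver transcription factors outside the delivered ones passed. In the fetal liver and bile duct list 4 of 17 were higher (Spp1, Krt19, Cd24a and Prom1) and Dlk1, named after its values were seen, was lower. Spp1, osteopontin, was 1643 against 272 FPKM and Krt19, a duct keratin, 359.7 against 62.4. Krt19 and Dsp were the 2 of 28 epithelial genes that were higher, and in the gut list Dpp4 and Cdh17 were higher and Krt20 lower. Median differences of the secreted, detoxification, liver factor, fetal and gut lists lay between 0.00 and 0.09 and took the other sign after quantile normalisation. In the inflammation list 4 of 19 genes were higher (Il1rn, Saa3, Cxcl1 and, named after its values were seen, Socs3) and Ccl2 was lower.

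With Mir, Snor and predicted genes skipped, the 5 largest positive differences after the delivered factors were in the following genes. Col10a1, the collagen of growth plate cartilage, was 152 FPKM against 1.05 (log2 difference 6.22), the collagenase gene Mmp13 115 against 1.16 (5.75) and the stromelysin gene Mmp3 454 against 11.2 (5.22). Slc4a9, a bicarbonate transporter gene listed at 0 in fibroblasts, was 60.6 FPKM, and Sprr1a, a cornified envelope gene, 72.2 against 0.380 (5.73). The largest differences downward, with the same genes skipped, were in Rps27 (-4.22), Adcyap1r1 (-3.40), the MAP kinase phosphatase gene Dusp5 (-3.38), Fam150a (-3.31), the AP-1 gene Jun (-3.28), the connexin gene Gjb3 (-3.19), the peptide hormone gene Apln (-3.18) and Plau, urokinase (-3.12). Rps27, which encodes a ribosomal protein, was at 129.9, 6.03, 77.3, 1.96, 68.8 and 6.46 FPKM from fibroblasts to liver. Whether these uneven levels are a difference of expression or of annotation or libraries was not settled. This comparison rests on 1 fibroblast library. Among genes taken by the naming rule, Rbp4, Cdh17, Hoxb3, Mylpf, S100b and Sox5 differed by less than 2-fold after quantile normalisation, and Ctgf and Ephx1 after median-ratio scaling.

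The comparison of day 14 with fibroblasts covers the net difference after conversion. Most genes measured in the secreted liver protein, epithelial and gut lists were higher at day 14 than in fibroblasts, and most contractile and matrix genes were lower. Alb was 2284 FPKM against 2.95, and alpha-fetoprotein (Afp, the fetal counterpart of albumin; chromosome 5, 90490737 to 90508907) 484 against 0.156. The trefoil peptide gene Tff1, a product of stomach surface cells (chromosome 17, 31161395 to 31165277), was 2009 against 0.553 FPKM. Collagen I (Col1a1; chromosome 11, 94936224 to 94953042) was 38.1 against 1512 FPKM, and smooth muscle actin (Acta2) 29.6 against 3548. Of 14107 genes, 2396 were called higher and 1691 lower, and 965 and 438 of these differed at least 4-fold. Calls were 58.6% higher, but 48.3% after quantile normalisation.

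**Figure D2:**
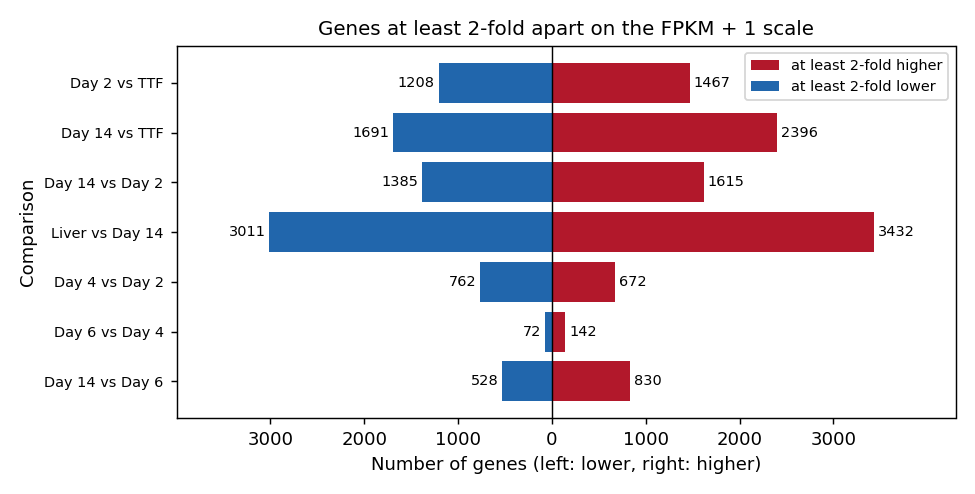
Number of genes, of 14107, at least 2-fold higher (bars to the right) and at least 2-fold lower (bars to the left) in each of 7 comparisons, with the pseudocount of 1. The step from day 4 to day 6 holds the fewest, 142 higher and 72 lower, and liver against day 14 the most, 3432 and 3011.

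Of 30 hepatocyte secreted proteins, 18 were higher at day 14 and none lower (median 2.95, above all 10000 random lists). Complement C3 was 532 against 0.223 FPKM, Trf 1177 against 0.930 and Cp 787 against 0.316. Metabolic enzymes differed less, with 8 of 30 higher and Ass1 lower (median 0.15, random lists -0.20 to 0.57). Aldob, which cleaves fructose 1-phosphate, was 59.2 against 0.168 FPKM, the ketone body enzyme gene Hmgcs2 31.1 against 0.0711 and the liver pyruvate kinase gene Pklr 7.24 against 0.0298. Of 30 detoxification and transport genes, 9 were higher and none lower (median 0.14, random lists -0.14 to 0.62), among them Sult1a1 at 28.6 against 0.189 FPKM and the sterol exporter gene Abcg5, listed at 0 in fibroblasts, at 8.15. The medians of these metabolic and detoxification lists were -0.01 after quantile normalisation. With the deposited values they lay at percentiles 54.0 and 45.5 of random lists, or 92.7 and 90.8 of lists matched on the 2 columns. Of 23 liver transcription factors, 8 were higher (median 0.47, random lists -0.19 to 0.62, at percentile 92.2, or 97.8 of lists matched on the 2 columns), led by Hnf4a, a regulator of hepatocyte identity, at 74.6 against 0.0176 FPKM, Nr1i2, the pregnane X receptor, at 11.9 and listed at 0 in fibroblasts, and Klf15 at 8.23 against 0.175. Gata6 and, named after its values were seen, Tbx3 were lower. In the fetal liver and bile duct list 12 of 17 were higher (median 2.84, above all 10000 random lists), among them Prom1 at 24.6 against 0.0439 FPKM, Ahsg at 60.99 against 0.324 and the imprinted gene Peg3 at 46.6 against 0.205, while Dlk1 was lower.

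Of 28 epithelial junction and keratin genes, 24 were higher and none lower (median 2.65, above all 10000 random lists). E-cadherin (Cdh1) was 123 against 0.0521 FPKM, Krt18 162 against 0.677, and Krt8, listed at 0 in fibroblasts, 86.5. Of 20 intestinal and gastric genes, 16 were higher (median 1.70, above all 10000 random lists) and 1, the stem cell gene Lgr5, named after its values were seen, was lower. Over all 30 listed genes the median was 1.37 FPKM at day 14 and 0 in fibroblasts. Reg3g, an antibacterial lectin of gut epithelium, was 951 against 0.391 FPKM, the trefoil gene Tff3, listed at 0 in fibroblasts, 1108, and the galectin gene Lgals4 317 against 0.547. With Mir, Snor and predicted genes skipped, the 8 genes with the largest positive difference were Saa3, an acute phase apolipoprotein (11.29, 7716 FPKM), the protease inhibitor gene Spink3 (10.72, 7001 FPKM), Tff1 (10.34), the gastrokine gene Gkn2 (10.20, 1482 FPKM), Tff3, the aldehyde dehydrogenase gene Aldh3a1 (9.93, 1029 FPKM), clusterin (Clu, 9.77, 3582 FPKM) and the galectin gene Lgals2 (9.75, 1028 FPKM).

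Of 15 myofibroblast and smooth muscle genes, 14 were lower and none higher, with a median of -4.34 (below all 10000 random lists). The exception, Des, was 0.479 against 0.358 FPKM. The actin-binding genes Tagln (-7.86, 9.63 against 2463 FPKM) and Cnn1 (-7.81), and Actg2 (-7.51) showed the largest differences downward with the same genes skipped, followed by the retinoid-binding gene Crabp1 (-7.36), cyclooxygenase 2 (Ptgs2, -7.25), the interleukin 33 receptor gene Il1rl1 (-7.12), the BMP antagonist gene Grem2 (-7.06) and Acta2 (-6.86). Of 29 extracellular matrix genes, 22 were lower (median -3.35, below all 10000 random lists), including Thy1, a fibroblast surface marker, at 2.995 against 408 FPKM and Col5a2 at 9.296 against 787. Dcn, decorin, and Pdgfra were higher, the first at 33.3 against 3.798 FPKM. Of 21 mesenchymal transcription factors, 15 were lower and none higher (median -1.70, below all 10000 random lists), such as Prrx2 at 0.681 against 55.9 FPKM and Twist2 at 0.874 against 28.6. Cell cycle genes were lower in 19 of 30 cases and higher in none (median -1.16, below all 10000 random lists), such as Plk1 at 17.5 against 60.8 FPKM. Interferon response genes were higher in 18 of 25 cases and lower in none (median 1.41, above all 10000 random lists), such as Oas1a at 14.7 against 1.13 FPKM. In the inflammation list 10 of 19 were higher (median 1.002, random lists -0.37 to 0.52), including Lcn2, an iron-sequestering acute phase protein gene listed at 0 in fibroblasts, at 832 FPKM, and Ptgs2 was lower.

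Hox genes differed in both directions at day 14, with 4 of 27 higher (Hoxc4, Hoxc5, Hoxc6 and Hoxc9) and Hoxc13 and, named after its values were seen, Hoxb9 lower, and a median of -0.03 (-0.43 after quantile normalisation). In the p53 and senescence list 4 of 16 were higher (Trp53inp1, Perp, Gadd45a and, named after its values were seen, Bbc3), and Cdkn2a was lower at 70.8 against 178 FPKM (median 0.31, random lists -0.58 to 0.36). Of 24 cholesterol synthesis genes, 4 were higher (Pcsk9, Stard4, Tm7sf2 and Dhcr24) and none lower (median 0.15, random lists -0.55 to 0.19), and of 27 chromatin genes 3 were higher (the DNA demethylase genes Tet2 and Tet3 and the methylase gene Dnmt3a) and none lower (median 0.11, random lists -0.41 to 0.36). Among 20 widely expressed control genes B2m was higher and Actb and Gapdh were lower, Actb at 774 against 3344 FPKM, and the median of -0.43 became -0.03 after quantile normalisation. Markers of other cell types gave small counts against fibroblasts, and few members of some lists were measured. These were 3 of 12 skin, 4 of 12 muscle and 4 of 12 cartilage markers. Measured too were 6 of 10 fat, 3 of 10 glial and neuronal and 5 of 9 red blood cell markers. At day 14 the macrophage markers Cd14 (111 against 3.68 FPKM) and Mpeg1 (22.2 against 0.0885) were higher of 13 measured, the endothelial markers Lyve1 and Pecam1 of 12, the red blood cell marker Alas2 of 5, the muscle markers Mylpf and Tnni2 of 4, the cartilage marker Comp of 4, the fat markers Lpl (99.1 against 2.42 FPKM) and Adipor2 of 6 and the glial marker S100b of 3. The skin marker Sbsn (of 3), the muscle marker Acta1 and the neuronal marker Tubb3 were lower. At day 2 the higher ones were Mpeg1, Lyz2, Cd14, Mylpf, Sox5, Fabp4, Mbp and S100b and the lower ones Sbsn, Acta1 and Tubb3, and no endothelial or red blood cell marker passed in either direction. Among control genes at day 2, B2m was higher and Tfrc lower (median -0.22). At day 14 the differences of Alas2, Comp, Dnmt3a, Gapdh, Hoxc4, Hoxc5, Mylpf, Pecam1, Tet3 and Tnni2 were under 2-fold after quantile normalisation.

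The comparison of day 14 with day 2 leaves out the single fibroblast library and sets the late cells against cells that already held the factors but were in the first medium. Most genes measured in the secreted liver protein, epithelial and gut lists were again higher late, and most matrix and myofibroblast genes lower. Of 14107 genes, 1615 were called higher and 1385 lower, and 634 and 399 of these differed at least 4-fold. After quantile normalisation the balance turned, to 1406 higher and 1652 lower. With Mir, Snor and predicted genes skipped, the largest positive differences were in Tff1 (10.71), Tff3 (listed at 0 at day 2), Gkn2 (9.94), Reg3g (9.76), Saa3 (9.75), Lgals2 (9.72), the amylase gene Amy2a5 (9.68) and Lcn2 (9.42), and the largest negative ones in Crabp1 (-7.56), the platelet chemokine gene Ppbp (-7.18), Thy1 (-6.97), Ptgs2 (-6.58), Tagln (-6.56), Cnn1 (-6.51), Actg2 (-6.50) and the myosin light chain gene Myl9 (-6.45).

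Secreted proteins were higher at day 14 than at day 2 for 18 of 30 genes (median 2.93, above all 10000 random lists), such as haptoglobin (Hp, 433 against 0.0847 FPKM) and apolipoprotein A-I (Apoa1, 521 against 0.590 FPKM). Epithelial genes were higher for 22 of 28 (median 2.34, above all 10000 random lists), gut genes for 14 of 20 with Lgr5 lower (median 1.51, above all 10000 random lists), and fetal liver genes for 10 of 17 with Dlk1 lower (median 2.40, above all 10000 random lists). Liver transcription factors were higher for 6 of 23 (median 0.40, random lists -0.22 to 0.46, at percentile 94.7, or 99.5 of lists matched on the 2 columns), detoxification genes for 6 of 30 (median 0.06, random lists -0.13 to 0.45) and metabolic enzymes for 5 of 30. The latter were Aldob, Hmgcs2 and Pklr and, named after their values were seen, Acsm1 and Tdo2, while Ass1 and Fah were lower (median 0.05). Extracellular matrix genes were lower for 24 of 29 with Dcn alone higher (median -2.94, below all 10000 random lists), myofibroblast genes for 14 of 15 (median -4.29, below all 10000 random lists) and mesenchymal transcription factors for 13 of 21 (median -1.11, below all 10000 random lists). Interferon response genes were lower for 15 of 25 and higher for Mx1 (median -1.13, below all 10000 random lists), Isg15 at 15.1 against 254 FPKM. Cholesterol synthesis genes were lower for 7 of 24 and higher for none (median -0.65, random lists -0.42 to 0.16), Mvk and Fdps among them, at 13.1 against 47.7 and 133 against 366 FPKM. The day 2 column enters this comparison and that of day 2 with fibroblasts with opposite signs, which alone favours opposite directions. In the cell cycle list Mki67, Mcm3, Mcm7 and Top2a were higher and Mcm6 and, named after its values were seen, E2f1 lower, of 30 (median 0.52, random lists -0.24 to 0.30). Mki67, a proliferation marker, was 30.3 at day 14, 10.98 at day 2 and 39.3 FPKM in fibroblasts. Inflammation genes were higher for 7 of 19 and lower for Ptgs2 (median 0.61, random lists -0.29 to 0.38), chromatin genes higher for Tet2 and Tet3 of 27 (median 0.55, random lists -0.28 to 0.31), and Hox genes lower for 5 of 27 (median -0.43, random lists -0.13 to 0.46). These Hox genes were Hoxc13, Hoxb2, Hoxb8, Hoxb13 and, named after its values were seen, Hoxa13. The medians of the p53 list (-0.13) and of the control genes (-0.21) took the other sign after quantile normalisation, at 0.06 and 0.12, and Mcm6 and Tet2 then differed by less than 2-fold.

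The overlap with the difference between liver and fibroblasts, which shares no column with this comparison, was counted gene by gene. Of the 1615 genes higher at day 14 than at day 2, 775 were also higher in liver than in fibroblasts, where 483 would be shared by independent picks, and 159 were lower in liver, against 374. Of the 1385 genes lower at day 14, 864 were lower in liver than in fibroblasts, against 320.5 for independent picks, and 144 were higher, against 414. The early difference overlapped otherwise with that between liver and day 14, which also shares no column with it. Of the 1467 genes higher at day 2 than in fibroblasts, 364 were higher in liver than at day 14, against 357, and 483 lower, against 313. Of the 1208 genes lower at day 2, 151 were higher in liver, against 294, and 385 lower, against 258. The numbers for independent picks take no account of level. A gene under 1 FPKM in the column compared against can be called higher but not lower. Those columns were alike, with a Pearson correlation of 0.92 for fibroblasts and day 2 and 0.79 for fibroblasts and day 14. Level alone thus favours shared directions over opposite ones, and its part in these overlaps was not tested.

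Between successive days the differences were uneven, and the step from day 4 to day 6 was the smallest. Calls were 672 higher and 762 lower at day 4 than at day 2, 142 and 72 at day 6 than at day 4, and 830 and 528 at day 14 than at day 6. With a pseudocount of 0.1 these counts were 1232 and 1191, 424 and 155, and 1266 and 998. After quantile normalisation the last step was near even, at 784 higher and 727 lower. Over the 4 days, 3756 genes had a highest and a lowest value at least 2-fold apart. From day 2 to day 4 contractile genes were lower in 14 of 15 cases (median -2.94, below all 10000 random lists), Acta2 at 114 against 2054 FPKM. The matrix list was lower for 17 of 29 (median -1.40, below all 10000 random lists) and higher for Postn, Pdgfra and, named after its values were seen, Dcn, and 14 of 30 secreted proteins were higher (median 0.69, above all 10000 random lists), Kng1 at 2288 against 28.1 FPKM. Interferon genes were lower for 13 of 25 at day 4, with Ifit2 higher (median -1.04), and higher for 8 at day 6 than at day 4 (median 0.86), Ifit1 at 68.9, 33.1 and 68.5 FPKM at days 2, 4 and 6; the 2 steps share the day 4 column. Hnf4a was 0.203, 11.5, 29.7 and 74.6 FPKM at days 2, 4, 6 and 14, and Alb 3.15, 22.1, 89.2 and 2284. From day 6 to day 14, 21 of 28 epithelial genes (median 2.03, above all 10000 random lists), 12 of 20 gut genes (median 1.59, above all 10000 random lists) and 15 of 30 secreted proteins (median 0.97, above all 10000 random lists) were higher. Cdh1 was 3.55 FPKM at day 6 and 123 at day 14, and Krt8 0.174 and 86.5, while the gut genes Cdh17 and Dpp4 were lower. In that step 16 matrix and 8 myofibroblast genes were lower and none higher, and Kng1 was lower, at 632 against 2014 FPKM.

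The 3 largest differences each way were mostly in microRNA and other short RNA genes. With Mir, Snor, Rnu, Scarna and predicted genes left out, a choice made after the values were seen, they were Saa3 (8.71), Spink3 (8.09) and the protease inhibitor gene Serpina3n (7.98) upward and Sprr1a (-5.92), Ptgs2 (-5.78) and Cnn1 (-4.77) downward from day 2 to day 4. From day 4 to day 6 they were the antitrypsin genes Serpina1a (3.71), Serpina1c (3.46) and Serpina1b (3.45), paralogs that can share reads, upward, and Rps27 (-4.72, uneven over all columns), Ppbp (-2.02) and Snhg9 (a noncoding RNA of 183 nt, listed at 0 at day 6) downward. From day 6 to day 14 they were Reg3g (7.95), the gastrokine gene Gkn1 (7.30) and Tff1 (7.12) upward, and the protease gene Tll1 (-3.59), Gpnmb (-3.46) and Eif3j1 (-3.35) downward. Eif3j1 was at 11.3, 0.152, 10.6 and 0.137 FPKM at days 2, 4, 6 and 14, uneven as Rps27 was, and the same question stays open. It was at 0.129 FPKM in fibroblasts, so both genes set fibroblasts, day 4 and day 14 apart from days 2 and 6. If libraries or annotation differ between these columns, comparisons across them could be affected in other genes too, which was not tested.

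The comparison of liver with day 14 covers the distance that remained. Liver was higher in nearly all genes of the 3 hepatocyte lists and lower in most genes of the fetal, gut, matrix and cell cycle lists. Alb was 89065 FPKM in liver against 2284 at day 14. Apolipoprotein A-II (Apoa2) was 28797 against 1.32, and the drug-metabolising gene Cyp2e1 10919 against 0.290. Afp stood the other way, at 1.46 against 484 FPKM. Of 14107 genes, 3432 were called higher in liver and 3011 lower, and 1708 and 1323 of these differed at least 4-fold. After quantile normalisation the balance turned, to 2931 higher and 3452 lower.

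**Figure D3:**
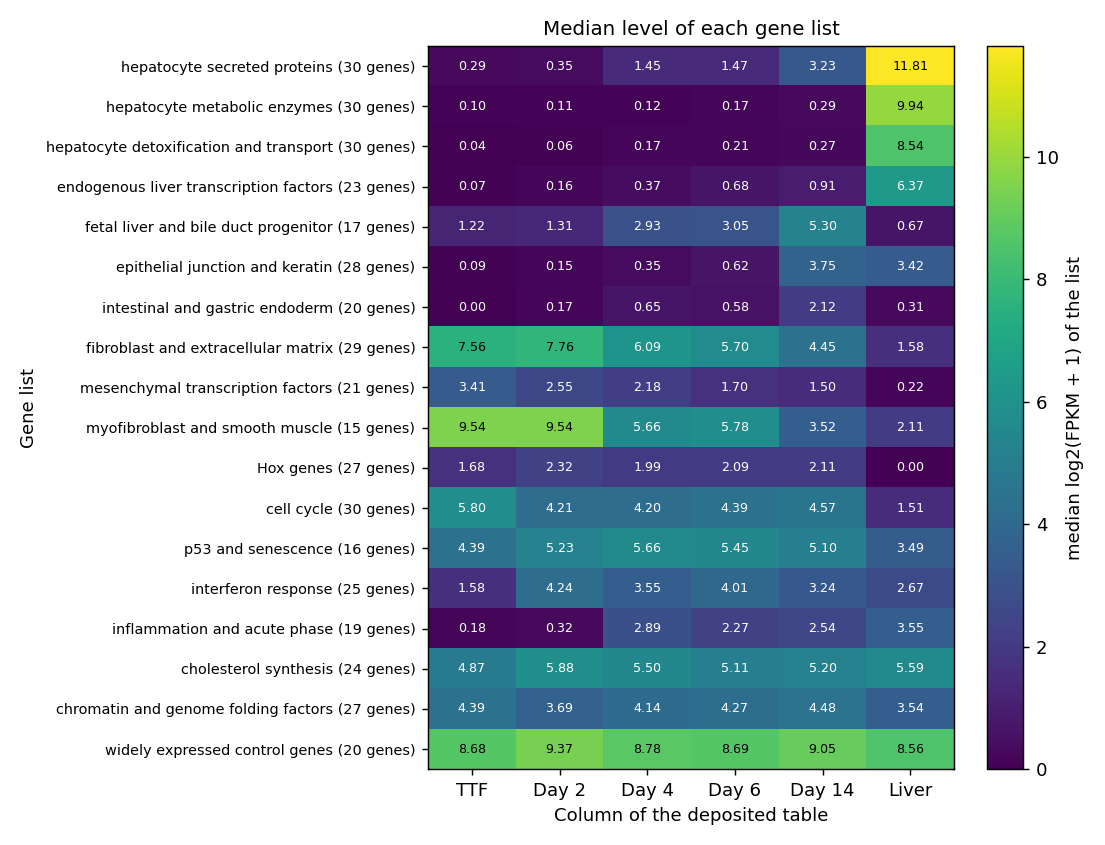
Median log2(FPKM + 1) of each gene list, other than the markers of other cell types, in the 6 columns, written in each cell and shown by colour. The hepatocyte secreted, metabolic and detoxification lists are highest in liver, and the myofibroblast and extracellular matrix lists are lower at day 14 than in fibroblasts.

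Of 30 secreted proteins, 29 were higher in liver (median 7.40, above all 10000 random lists), and the other, Cp, was 613 against 787 FPKM. Apoc1 and Apoc3 showed the largest differences of the list after Apoa2, Apoc3 at 8346 against 0.146 FPKM. All 30 metabolic enzymes were higher (median 8.52, above all 10000 random lists), such as Pck1, the entry enzyme of gluconeogenesis, at 5082 against 0.363 FPKM and Mat1a, which makes S-adenosylmethionine, at 2367 against 0.0635. All 30 detoxification and transport genes were higher (median 7.79, above all 10000 random lists), Cyp3a11 at 4232 against 0.0636 FPKM. Of 23 liver transcription factors, 22 were higher (median 4.15, above all 10000 random lists), such as Nr1i3, the constitutive androstane receptor, at 304 against 0.231 FPKM and Ppara at 121 against 0.421, and Xbp1, named after its values were seen, passed in neither direction. With Mir, Snor and predicted genes skipped, the 8 largest positive differences were Apoa2 (13.60) and 7 major urinary protein genes, Mup20 (14.05), Mup7 (13.59), Mup3 (13.59), Mup19 (13.44), Mup10 (13.39), Mup14 (13.32) and Mup2 (13.32). These paralogs can share reads. The 8 largest negative ones, with the same genes skipped, were Spink3 (-11.48), Aldh3a1 (-9.72), Gkn2 (-9.68), Reg3g (-9.55), Amy2a5 (-9.53), the cornified envelope gene Sprr2a1 (675 FPKM at day 14, listed at 0 in liver), the neutrophil chemokine gene Cxcl5 (614 FPKM, likewise at 0) and Lgals2 (-9.16).

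Fetal liver and bile duct genes were lower in liver for 14 of 17 and higher for Ahsg alone (median -4.18, below all 10000 random lists), with Cd24a at 1.61 against 294 FPKM. Gut genes were lower for 14 of 20 (median -2.12, below all 10000 random lists) and higher for Fabp1, Dpp4, Anpep and, named after their values were seen, Fabp2 and Lgr5. Fabp1, the fatty acid binding protein of liver and gut, was 22907 against 1.78 FPKM. Epithelial genes went both ways, 5 of 28 higher and 11 lower (median -0.22, random lists -0.47 to 0.82), with the tight junction gene Cldn3 at 88.4 and Cdh1 at 7.54 FPKM in liver against 3.41 and 123. Cell cycle genes were lower for 29 of 30 and higher for none (median -3.13, below all 10000 random lists), Top2a at 0.273 against 51.3 FPKM. Matrix genes were lower for 22 of 29 (median -2.21, below all 10000 random lists), with Dcn and, named after its values were seen, Lum higher, and vimentin (Vim) was 22.8 against 567 FPKM. Mesenchymal factors were lower for 9 of 21 and higher for Tcf21 (median -0.84), named after its values were seen, myofibroblast genes lower for 8 of 15 and higher for Des (median -1.41), and Hox genes lower for 23 of 27 (median -1.60). The p53 list was lower for 11 of 16 and higher for Perp (median -2.004), the chromatin list lower for 8 of 27 (median -0.66), the interferon list higher for 4 and lower for 7 of 25 (median -0.44), the inflammation list higher for 7 and lower for 10 of 19 (median -1.002), and the cholesterol list higher for 11 and lower for 4 of 24 (median 0.51).

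Markers of other liver cell types were higher in liver beside the hepatocyte genes, for 11 of 13 macrophage markers (median 5.36), 11 of 12 endothelial markers (median 3.68) and 5 of 5 red blood cell markers (median 9.16). Clec4f, a Kupffer cell lectin, was 95.6 FPKM in liver and 0 in every other column, and the haemoglobin gene Hba-a1 948 against 0.0921; haemoglobin paralogs can share reads. Of the other marker lists, liver was higher for 3 of 4 cartilage, 3 of 6 fat, 1 of 3 skin, 1 of 4 muscle and 0 of 3 glial and neuronal genes. The higher ones were Alpl, Sox5, Chad, Adipor2, Cidec, Cfd, Lor and Des, and Comp, Lpl, Sbsn, Tnni2, S100b and Tubb3 were lower. Control genes were higher in 3 cases (B2m, Sdha and Hmbs) and lower in 3 (Actb, Tfrc and, named after its values were seen, Ywhaz), and their median of -0.13 became -1.10 after quantile normalisation, which also left B2m, Sdha, Comp and Tubb3 under 2-fold. This comparison rests on 1 liver library, whose total FPKM was also the largest. Xist was 0.0941 FPKM in liver against 32.6 at day 14, and the Y-linked gene Ddx3y 28.9 against 16.5, both named after their values were seen. The Y-linked genes Kdm5d, Uty and Eif2s3y, named likewise, were 4.58, 4.53 and 61.3 FPKM in liver and 5.51, 5.42 and 19.1 at day 14. Day 14 held Xist beside Y-linked RNA, while liver held Y-linked RNA with Xist near 0. The sex makeup of the cells may thus differ between the 2 columns, and the comparison does not separate it from the distance to liver.

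How close each day lay to liver was counted on genes set by the 2 end columns. Of 2305 genes at least 4-fold higher in liver than in fibroblasts, 18.96%, 28.0%, 30.2% and 40.3% were at least 2-fold above fibroblasts at days 2, 4, 6 and 14; with a pseudocount of 0.1 the share at day 2 was 32.4%. Of 1556 genes at least 4-fold lower in liver, 31.2%, 49.2%, 50.6% and 54.8% were at least 2-fold below fibroblasts. Over all 14107 genes, 10.4% and 17.0% were at least 2-fold above fibroblasts at days 2 and 14, and 8.56% and 12.0% at least 2-fold below. A 2-fold difference can be a small part of the distance to liver. The median share of the log2 difference between liver and fibroblasts that was covered was 3.92%, 8.08%, 9.56% and 18.1% for the liver genes. For the fibroblast genes it was 12.6%, 30.0%, 31.2% and 35.4%. The fibroblast column serves both to pick these genes and to score them. With genes picked on liver against day 2 instead, the shares at day 14 were 32.7% of 2008 and 39.6% of 1539 genes. At day 4 the liver share was then 18.7%, and the fibroblast shares at days 4 and 6 were 30.1% and 32.4%. Of these fibroblast genes 19.2%, 18.8% and 12.7% were at least 2-fold above fibroblasts at days 4, 6 and 14. The shares at day 2 are not read here, since the day 2 column picked the genes. The covered part of the log2 difference also depended on the setting. At day 14 it was 8.97% for liver genes and 26.6% for fibroblast genes picked on liver against day 2. With genes picked on liver against fibroblasts at a log2 difference of 3, it was 13.1% and 34.8%. With a pseudocount of 0.1 it was 27.9% and 28.4%. For liver genes at days 2, 4 and 6 it was 1.82%, 3.92% and 5.65% at a log2 difference of 3. Of the 965 genes at least 4-fold higher at day 14 than in fibroblasts, 203 lay within 2-fold of liver, 165 were at least 4-fold below it and 418, or 43.3%, at least 4-fold above it. The genes above both ends included Spink3, Aldh3a1, Gkn2, Amy2a5, Reg3g and Afp. Across the 14107 genes, Pearson correlation of log2(FPKM + 1) with liver was 0.431 for fibroblasts and 0.455, 0.491, 0.496 and 0.531 for days 2, 4, 6 and 14. Days 4 and 6 had 0.982, the highest of the 15 pairs of columns computed. Genes are not independent replicates, so no p-value was attached.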

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

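The selection of liver and fibroblast genes on day 2, random lists matched on the 2 columns compared, and leaving out genes under 200 nt were chosen after the data were seen; the other alternatives were fixed in advance. No paired analysis was possible because the table holds 1 value per group and the labels pair no libraries. For the same reason limma with robust variances or without a minimum difference, camera and fry, the F test over days, the replicate block, fits of the 8 induction-day libraries alone and leaving out each library in turn were not run.

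Leaving out the filter could not change a count, since a gene under 1 FPKM in every column cannot be 2-fold apart on this scale. The 17 counts of genes stayed within 1.5 times their value under the stricter filter, both scalings and without short genes. With a pseudocount of 0.1, 10 did, and 7 were larger: 2443 genes higher at day 2 than in fibroblasts, 1232 higher and 1191 lower at day 4 than at day 2, 424 and 155 at day 6 than at day 4, and 1266 and 998 at day 14 than at day 6. A smaller pseudocount widens differences near 0 FPKM by construction. All 8 shares of liver and fibroblast genes at least 2-fold toward liver stayed within 1.5 times under a difference of 3. The covered part of the log2 difference is not among these shares, and for liver genes it varied more. With a pseudocount of 0.1 the liver share at day 2 was 32.4%, and the other 7 stayed within 1.5 times. With genes picked on liver against day 2, the liver shares were 9.46% at day 2 and 18.7% at day 4, the fibroblast shares 12.1%, 30.1% and 32.4% at days 2, 4 and 6, and the other 3 stayed within 1.5 times. The fibroblast column no longer picks the genes, but the day 2 column both picks and scores at day 2, which lowers the day 2 shares (25.2% of the fibroblast genes lay the other way).

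Of 484 differences of named genes, a pseudocount of 0.1 moved 248 by more than 1.5-fold and quantile normalisation 49. Of 107 list medians these moved 35 and 5, the latter all between liver and day 14. No called difference of a named gene took the other sign under the settings run. A pseudocount or a filter cannot change a sign, so only the scalings could have shown this. Of 104 positions of lists among random lists, 46 lay outside the central 95% when matched on all columns, 51 when matched on the 2 columns, and 44 under both. Those outside only with the second matching were the liver transcription factors (day 14 against fibroblasts and against day 2), the p53 list (day 2 and day 14 against fibroblasts), cholesterol synthesis and cartilage markers (day 14 against fibroblasts) and the control genes (liver against day 14); those outside only with the first were mesenchymal transcription factors (liver against day 14) and glial and neuronal markers (day 2 against fibroblasts). Depth limits the low values: in liver, at about 5.83e+06 fragments, a gene of low level listed at 0 cannot be called absent. Depth does not account for 0 in liver for an entry abundant in every other column, such as Mir692-2 (11469 to 20585 FPKM).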

Other observations

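Genes in this part were chosen after their values were seen. The tissue lists were written after the top genes were seen and before the levels of the lists were computed; the test of short length was chosen after its result was seen.

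A group of 401 genes was at least 2-fold higher at day 2 than both in fibroblasts and at day 14. It held the gut and brain peptide gene Cck, at 138, 470.5, 21.03, 18.5, 6.47 and 0 FPKM from fibroblasts to liver, the matrix gene Thbs2, at 36.6, 220.3, 107, 51.9, 5.34 and 0.770, the imprinted noncoding gene Meg3, at 54.2, 173, 59.9, 28.99, 3.15 and 18.7, and Cthrc1, a collagen repeat gene of wound repair, at 16.7, 144, 71.1, 37.4, 11.4 and 0. A smaller group of 82 genes was at least 2-fold higher at days 4 and 6 than at days 2 and 14, and 31 genes were at least 4-fold lower at day 14 than at both ends.

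Single genes stood above both ends at day 14. Clca3, a goblet cell protein gene, was 492 FPKM at day 14 against 0.0268 in fibroblasts and 0.0557 in liver, the chitinase-like gene Chil1 309 against 0.0495 and 0.411, the secretoglobin gene Scgb3a1 155 with 0 at both ends, and the mucosal chemokine gene Cxcl17 275 against 0.267 and 0. The tetraspanin gene Tspan8 was 348 at day 14 and already 23.4 at day 2. Rps27 was high at days 4 and 14 (77.3 and 68.8 FPKM) and low at days 2 and 6 (6.03 and 1.96), while Eif3j1 stood the other way, at 0.152 and 0.137 against 11.3 and 10.6. Mir692-2 was the most abundant entry of every column but liver, at 19373 FPKM in fibroblasts, and was listed at 0 in liver. Xist was 19.7 FPKM in fibroblasts, 32.6 at day 14 and 0.0941 in liver, and the Y-linked gene Ddx3y 9.61, 16.5 and 28.9.

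Stomach and gut genes reached high levels at day 14. Of a list of 15 gastric surface mucous genes, written after such genes were seen among the largest differences and so no test of the pattern, 14 were at 1 FPKM or more at day 14, with Tff1 at 2009, Gkn2 at 1482 and Psca at 265 FPKM; 3 of the 15 are in the fixed lists, and 4 are at 1 FPKM or more in liver. RNA from stomach tissue, pancreas or small intestine could have entered the day 14 libraries, but the median was 0.0371 FPKM over 10 chief and parietal cell genes (highest Pgc, 4.57), 0.207 over 18 pancreatic acinar genes (highest Sycn, 22.1) and 0.148 over 16 enterocyte and Paneth genes (highest Dgat1, 17.6). Of these, 0, 3 and 5 genes are at 1 FPKM or more in liver and 0, 1 and 1 in fibroblasts, and 3 of the last list are in the fixed lists. The acinar list left out Amy2a5, Amy2b and Spink3, acinar genes at 983, 148 and 7001 FPKM at day 14; with these 3 added after their values were seen the median over 21 genes was 0.261, 16 were under 1 FPKM, and Cpa1, Cel and Pnlip were listed at 0, so pancreatic tissue does not account for them, and their own high levels stay unexplained. The authors' scaling is also unlikely as the cause, since the intestinal and gastric list kept a median difference of 1.46 after quantile normalisation. A gastric surface program in the induced cells themselves remains a candidate explanation, open because the columns are of whole cultures and do not show which cells hold the RNA. The fibroblast column, with the 3 factors near 0, had none of the 15 genes at 1 FPKM or more, but it also differs in virus and time.

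Short RNA genes held the largest differences between successive days. Between days 4 and 6, 42.7% of 75 genes under 200 nt were at least 2-fold apart against 1.26% of those of 500 nt or more, a ratio of 33.8. This is consistent with the coarse steps that few fragments give in FPKM of short genes. Whether these RNAs kept a steady course stays open: 15.6% of the 32 genes 2-fold apart between days 4 and 6 differed the same way from day 6 to day 14, but the 2 steps share the day 6 column and 13 of the 18 genes lower at day 6 are listed at 0 there and cannot be lower still. The libraries were made with an mRNA kit, and whether these values come from the short RNAs themselves is open too. No other biological explanation was tested.

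Actin and smooth muscle genes were lower at day 4 than at day 2. The authors' scaling is unlikely as the cause, since the median of the list was -2.87 after quantile normalisation. Whether serum response factor (SRF) sets this stays open: 18 actin and SRF target genes outside that list had a median of -1.44, but they were listed after the actin genes were seen and are largely actin cytoskeleton genes, so they do not part SRF from another cause, and SRF was not measured beyond its RNA (Srf, 23.2 and 10.5 FPKM). The change of medium after 48 hours cannot be told apart from time, because 0 columns of induced cells past day 2 stayed in the first medium.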
